A study of Caenorhabditis elegans with 6 samples.

How the data were processed

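Adult nematodes of the wild-type strain N2, a gst-35 knockout strain and a gst-35 overexpression strain were compared on day 5 of adulthood, with 2 libraries per group and 6 in all. Per the labels' protocols the animals were grown at 20 °C on agar plates, washed off in buffer and extracted with Trizol, and libraries were made with a kit whose strand setting is not stated. The title and the design text call the first mutant strain a knockout and its genotype label a knockdown, and knockout is used here. The labels number the replicates within each group and do not say that they came from separate cultures. Each library was placed in its group from its title.

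The authors deposited a table with raw read counts per gene and library, and per the submitters' processing notes the reads had been aligned with HISAT2 2.0.5. The counting tool, the genome build, the annotation and the use of strand are not given in the sources used here, so reads of overlapping, antisense and near-identical genes, such as members of the fbxb, skr, clec, col and msp families, may be split differently from their true source. The deposited FPKM values equal the counts divided by the deposited gene length and by a library total that was 0.923 to 1.07 times the sum of the counts. They were used only to print gst-35. The authors' table also holds log2 fold changes, p-values and adjusted p-values for overexpression against wild type and against knockout, made with a tool not given in the sources used here. Their lists of changed genes match an unadjusted p under 0.05 with an absolute log2 fold change over 1. 8 further columns of per-sample values matched no listed sample and were not used. The table has 46845 genes, 256 of them unnamed loci that the authors' annotation added.

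Counts were tested with edgeR 4.0.16 in R 4.3.3 with the quasi-likelihood F test (two-sided), TMM scaling, a low-count filter (filterByExpr, minimum count 10, minimum total 15) and a prior count of 0.125. It kept 14983 genes, which held at least 99.874% of the counts of each library. All 6 libraries shared a single estimate of the spread, with a common biological coefficient of variation of 19.1%. Adjusted p-values are Benjamini-Hochberg values over the tested genes of a comparison, and a gene is said to have risen, fallen or changed where its adjusted p was under 0.05. CPM values are reads scaled by the TMM-scaled library sizes. They are given as mean ± SD of 2 libraries, and folds are those of the fit. SE is that of the log2 fold change. Library totals ran from 17797090 to 21468239 reads. In simulated data with the means and library sizes of these samples, 105 genes were changed 2-fold and 95 genes 4-fold. edgeR recovered 52.4%, 54.3% and 49.5% of the former and 90.5%, 91.6% and 92.6% of the latter. These shares are for knockout against wild type, overexpression against wild type and overexpression against knockout. False calls numbered 4, 4 and 6 among 145, 148 and 146 calls of 14983 genes. Simulated genes of like expression had the same spread and no library stood apart, so power and false calls in the data may differ. Only genes with a mean of at least 1 CPM were changed, so the recovered shares do not cover weaker genes.

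The design, the alternatives, the rule for named genes and 37 gene lists were chosen before the data were examined. Lists covered glutathione S-transferases and other detoxification and antioxidant enzymes, SKN-1 and DAF-16 targets, the p38 pathway and its effectors, immune effector families, the intracellular pathogen response, skr and other ubiquitin ligase genes, lysosomal hydrolases and membrane genes, V-ATPase, autophagy, heat shock proteins, chaperones, mitochondrial stress, nuclear and mitochondrial respiratory chain genes, proteasome, ribosomal proteins, lipid metabolism, vitellogenins, insulin-like peptides, histones, markers of intestine, muscle, pharynx and neurons, collagens, moulting genes, and sperm, germ cell, oocyte and embryo genes. gst-35 was left out of every list. The 36 lists with at least 5 tested members were tested with camera (limma 3.58.1) at a preset correlation of 0.01, adjusted over the lists, and again with the correlation estimated from the data, under which none of the lists was called in any comparison. fry was run beside it. Its directional p asks whether the genes of a list move on balance in a single direction, its mixed p whether they change in either direction, and neither compares a list with other genes. Its lowest directional adjusted p was 0.204, 0.0714 and 0.244 in the 3 comparisons, and its mixed p called 16, 27 and 22 lists. Camera was tested on simulated data in which ribosomal proteins had been raised in overexpression against wild type, and called that list and 0 others without shared members. The simulated genes were drawn independently of each other, so this run does not test the preset correlation. In the data the estimated correlation of ribosomal proteins in that comparison was 0.217. List medians use fitted fold changes. Where members had 0 reads in a group, medians were also computed with a floor of 3 reads over the group's libraries, which moved the collagens in the knockout from 0.15 to 0.13 and the other fixed lists by less, and the math family between the edited strains from -0.5721 to -0.597.

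Genes are named by a fixed rule: gst-35, the 10 largest changes each way among changed genes with a mean of at least 5 CPM and no overlap between the groups' libraries (chance gives no overlap in 33.3% of genes with 2 against 2), members of the lists with the smallest p, pmk-1 and the skr genes, and genes within 20 kb of gst-35. The intervals on gst-35 ratios are exact 95% intervals from the reads and cover counting error only. Coordinates are those of the deposited table, whose build is not given in the sources used here. gst-35 was also looked up in Ensembl release 115 (WBcel235), in which 24974 of 40647 shared gene names had the same coordinates and 95.4% lay within 1000 bases. Overlap between the comparisons with wild type was set beside 20 simulations of unchanged groups against the same wild-type libraries. Intervals on medians in the closing part are bootstrap intervals of 2000 draws over genes.

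The alternatives were DESeq2 1.42.0, limma-voom, median-of-ratios size factors, library totals alone, no low-count filter, at least 5 CPM in 2 libraries, only the groups compared, the replicate number as a block, a 2-fold minimum and each library left out in turn. With a library left out, its partner is assumed to vary like the libraries of the other groups.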

Results

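Gene expression was measured by RNA sequencing in the nematode Caenorhabditis elegans on day 5 of adulthood, in the wild-type strain N2, a gst-35 knockout strain and a gst-35 overexpression strain, with 2 libraries per strain. gst-35 encodes a glutathione S-transferase, a member of an enzyme family that couples glutathione to electrophiles, and the comparisons ask how its level bears on the healthy part of the animal's life. The counts summed to 19002752 and 21468239 reads in wild type, 18816755 and 19691807 in the knockout, and 19581064 and 17797090 in the overexpression strain. Ribosomal RNA genes took 0.528% and 0.517% of the counts in wild type, 0.240% and 0.405% in the knockout, and 0.145% and 0.0856% in the overexpression strain. At least 1 read was assigned to 19913 and 20113 genes in wild type, 18651 and 19938 in the knockout, and 18610 and 17759 in the overexpression strain. The first principal component of the log2 CPM values held 49.4% of the variance and placed the wild-type libraries at -46.2 and -54.1, the knockout libraries at 1.62 and -25.9, and the overexpression libraries at 52.7 and 71.9. On the second component, with 23.4% of the variance, knockout replicate 1 stood at -62.4 and the other libraries between -23.4 and 34.03. Replicates correlated at 0.979 to 0.981 across genes, which are not independent replicates, and differed by more than counting noise in each group. The labels give no separate cultures for the replicates, so p-values measure only the spread between these libraries, which may be technical.

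gst-35 itself (Y1H11.2) had 98 and 102 reads in wild type, 3 and 11 in the knockout, and 5335 and 4607 in the overexpression libraries. In CPM, reads scaled to a common library size, these were 4.60 ± 0.158 (SD, n = 2) in wild type, 0.367 ± 0.283 in the knockout and 278 ± 13.4 in the overexpression strain. The knockout level was 8.16% of wild type (exact 95% interval for counting error only, 4.38% to 14%), and the overexpression level was 60.7-fold that of wild type (52.8 to 70.2). The log2 fold changes were -3.60 in the knockout (SE 0.33, adjusted p = 0.000337) and 5.92 in the overexpression strain (SE 0.22, adjusted p = 1.04e-07), and 9.51 between overexpression and knockout (SE 0.29, adjusted p = 1.04e-08). Without knockout replicate 2 the knockout value was -4.72 and without knockout replicate 1 it was -2.995. The authors' FPKM values were 6.33 and 6.01 in wild type, 0.226 and 0.740 in the knockout, and 386 and 355 in the overexpression libraries. The deposited table places the gene on the minus strand of chromosome II at 15183809 to 15185385. In the WBcel235 annotation it spans 15183807 to 15185389, with exon 1 at 15185218 to 15185389, exon 2 at 15183807 to 15184404 and an intron of 813 bases between them. The 5' untranslated region there has 12 bases and the 3' untranslated region 101 bases. The 6 glutathione S-transferase genes within 20 kb of it, gst-26, gst-27, gst-28, gst-29, gst-31 and gst-39, did not pass the test in any comparison. gst-26 stood at 6.44 ± 0.534 CPM in wild type, 9.37 ± 3.72 in the knockout and 8.47 ± 1.22 in the overexpression strain.

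**Figure D1:**
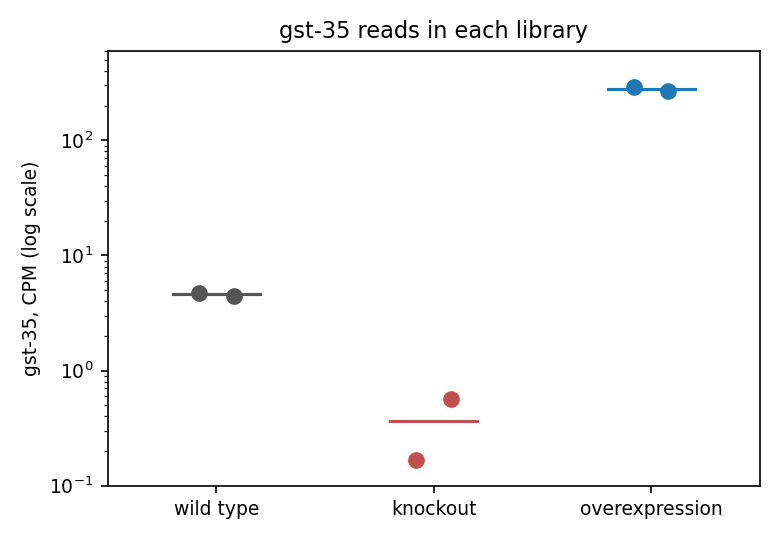
CPM of gst-35 in each library on a log scale, with a line at each group's mean of 2 libraries. Wild type stood at 4.60 CPM, the knockout at 0.367 and the overexpression strain at 278.

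In the knockout strain, 36 of 78 cytosolic ribosomal protein genes rose and 6 fell, 7 of 34 oocyte genes rose and 1 fell, and 7 of 105 fbxb genes, a family of F-box genes, fell. prdx-2, a peroxiredoxin, rose from 195 ± 2.60 to 454 ± 20.5 CPM (n = 2), 2.33-fold (log2 fold change 1.22, SE 0.12, adjusted p = 0.000381). col-19, an adult cuticle collagen, rose 3.22-fold to 249 ± 14.7 CPM, and perm-2, a component of the eggshell, rose 2.76-fold to 1192 ± 70.6 CPM. Of 14983 tested genes 661 differed from wild type, 447 higher and 214 lower, so that 67.6% of the changed genes were higher. That share was 78.6% (364 higher and 99 lower) without knockout replicate 1 and 51.9% (807 and 748) without knockout replicate 2, and between 61.1% and 73.6% without each of the other libraries. Among changed genes with a mean of at least 5 CPM, the largest rises were in F59B2.12 (7.84-fold), C55C3.3 (6.96-fold), clec-12 (6.17-fold), nspc-1 (4.58-fold), rmo-1 (4.39-fold), T10D4.6 (4.38-fold), ZK354.2 (4.35-fold), nspc-7 (4.25-fold), hmit-1.1 (4.20-fold) and F49F1.6 (3.83-fold). clec-12 belongs to the C-type lectins, nspc-1 and nspc-7 to a nematode-specific peptide family, and hmit-1.1 encodes a proton-coupled myo-inositol transporter. T10D4.6 stood at 102 ± 3.46 CPM against 23.2 ± 1.401 in wild type (SE of log2 0.16, adjusted p = 0.000208). After gst-35, the largest falls were in hsp-12.6 (7.87-fold lower), F59C12.4 (7.48-fold), Y37A1B.5 (7.23-fold), Y22D7AR.10 (5.89-fold), an unnamed locus of chromosome V that the authors' annotation added (5.23-fold), F46E10.2 (5.17-fold), F23D12.11 (4.65-fold), C10G8.4 (4.41-fold) and H19N07.3 (4.35-fold). C10G8.4 fell from 48.7 ± 3.35 to 11.03 ± 0.0731 CPM (adjusted p = 0.000337), and hsp-12.6, a small heat shock protein, from 15.3 ± 11.215 to 1.93 ± 1.94 CPM (adjusted p = 0.0306). Each library weighed on this comparison. With wild-type replicate 2 left out only 94 genes passed and with wild-type replicate 1 left out 229. Leaving out knockout replicate 2 gave 1555 genes, and leaving out overexpression replicates 1 and 2 gave 379 and 420. Without wild-type replicate 2 the adjusted p was 0.0503 for nspc-1, 0.163 for F46E10.2, 0.18 for the unnamed locus, 0.181 for hsp-12.6 and 0.326 for Y37A1B.5. With wild-type replicate 1 left out it was 0.0607 for rmo-1 and 0.0615 for F23D12.11, and the log2 fold change of F59B2.12 was 5.09. Without knockout replicate 1 it was 0.0508 for Y37A1B.5, and the log2 fold changes of clec-12 and F46E10.2 were 1.71 and -1.55. Without knockout replicate 2 those of hsp-12.6, F46E10.2 and rmo-1 were -4.76, -4.46 and 1.38. With overexpression replicate 1 left out the adjusted p was 0.0522 for F59B2.12, 0.0591 for hsp-12.6, 0.0786 for Y37A1B.5 and 0.0848 for F46E10.2. Without overexpression replicate 2 it was 0.0534 for hsp-12.6, 0.072 for Y37A1B.5 and 0.0778 for F46E10.2. With a 2-fold minimum 135 genes were higher and 148 lower. Scaled by library totals alone, 540 genes passed and 34.3% of them were higher. That scaling moved the median of all genes by -0.152 on the log2 scale in the knockout and by -0.174 in the overexpression strain, so directions below are relative to the median gene. Genes under 1 CPM, 2447 in number, had a median log2 fold change of -0.34 in the knockout, and the 4182 genes over 50 CPM one of 0.12, with 286 higher and 56 lower.

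Among the gene lists fixed before the data were examined, ribosomal proteins had the smallest camera p in the knockout, with 36 of 78 tested members higher and 6 lower (41 and 8 adjusted over the list alone). rpl-24.1 rose 3.103-fold and rpl-2 2.70-fold, while rpl-22 was 1.75-fold lower, and the list's median log2 fold change was 0.43 (camera adjusted p = 2.2e-20, adjusted p = 0.591 with an estimated correlation). Of 34 oocyte genes 7 rose and cpg-8 fell (21 and 1 adjusted over the list alone). perm-2 and cpg-2, a chondroitin proteoglycan of the eggshell, rose 2.76-fold and 1.55-fold, and the list was called at an adjusted p of 6.95e-11 (adjusted p = 0.663 with an estimated correlation). Germ cell genes were called upward with nos-2 and glh-1 among 25 past the test (4 higher adjusted over the list alone), and sperm genes with ssp-11 among 43 (0 adjusted over the list alone). Their medians were 0.18 and 1.01 (camera adjusted p = 0.00502 and 3.57e-06, adjusted p = 0.663 with an estimated correlation for both). Of 32 proteasome genes 3 rose (5 adjusted over the list alone), pbs-1 by 1.64-fold and pbs-6 by 1.55-fold (camera adjusted p = 0.00991, adjusted p = 0.675 with an estimated correlation). The vitellogenins, yolk proteins of the intestine, had a median of 0.40 with 0 of 6 past the test (2 higher adjusted over the list alone, camera adjusted p = 0.0385, adjusted p = 0.663 with an estimated correlation). Of 194 tested immune effector genes 17 rose and 5 fell (25 and 8 adjusted over the list alone), with clec-12 6.17-fold and clec-265 1.73-fold higher and fipr-2 and fipr-1 2.54-fold and 2.26-fold lower (camera up, adjusted p = 0.0456, adjusted p = 0.591 with an estimated correlation). Among 12 effectors whose basal expression needs pmk-1, 0 passed (2 higher adjusted over the list alone, median 0.26, camera adjusted p = 0.0457, adjusted p = 0.663 with an estimated correlation). The median of the vitellogenins was 0.103 without knockout replicate 1, 0.716 without knockout replicate 2 and 0.604 without wild-type replicate 1. That of the sperm genes was 0.512 without knockout replicate 1, 1.54 without wild-type replicate 1 and 0.526 without wild-type replicate 2, and that of the PMK-1 dependent effectors 0.557 without knockout replicate 2. Knockout replicate 1 and wild-type replicate 2 weighed on these calls. Without the former the camera adjusted p was 0.56 for vitellogenins, 0.236 for the pmk-1 dependent effectors, 0.351 for immune effectors and 0.0553 for the proteasome. There the adjusted p was 0.128 for cpg-8, 0.139 for nos-2 and 0.215 for ssp-11. Without the latter vitellogenins, pmk-1 dependent effectors and immune effectors stood at 0.051, 0.0819 and 0.0732. In the same setting cpg-2, cpg-8, nos-2, glh-1, ssp-11, pbs-1, pbs-6, fipr-1 and fipr-2 at 0.0954, 0.229, 0.294, 0.232, 0.225, 0.0906, 0.166, 0.156 and 0.0731. Without wild-type replicate 1 the adjusted p was 0.056 for cpg-2, 0.0553 for cpg-8, 0.0528 for nos-2, 0.176 for glh-1, 0.085 for ssp-11, 0.0627 for pbs-1, 0.102 for pbs-6 and 0.0773 for clec-265. Without overexpression replicates 1 and 2 ssp-11 stood at 0.0818 and 0.0697, nos-2 at 0.0693 and 0.0681 and glh-1 at 0.0786 and 0.0752. Without knockout replicate 2 glh-1 stood at 0.0792. Scaled by library totals the camera adjusted p was 0.0586 for germ cell genes and 0.174 for the proteasome, and the median of the immune effectors was -0.0049.

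The list of cullins, F-box and MATH domain genes, subunits of ubiquitin ligases, was called downward in the knockout with 8 of 381 members lower and 2 higher (3 and 1 adjusted over the list alone). The members that fell were F-box genes, 7 of them among 105 tested fbxb genes. fbxb-66 and fbxb-31 were 2.85-fold and 5.34-fold lower, and the cullin cul-3 and fbxc-50 were 1.56-fold and 1.66-fold higher. The list's median was -0.53 (camera adjusted p = 2.55e-07, adjusted p = 0.591 with an estimated correlation). Of 20 tested skr genes, Skp1-related subunits of the same ligases, skr-12, skr-19 and skr-7 fell, by 2.68-fold, 2.52-fold and 2.27-fold (8 lower adjusted over the list alone), and 17 did not pass (camera adjusted p = 0.000328, adjusted p = 0.663 with an estimated correlation). In the p38 pathway tir-1 was 2.15-fold and sek-1 1.59-fold lower among 8 genes (6 lower adjusted over the list alone, camera adjusted p = 5.7e-05, adjusted p = 0.591 with an estimated correlation). pmk-1 itself stood at 27.3 ± 2.98 CPM in wild type and 19.2 ± 1.14 in the knockout, a log2 difference of -0.51 that did not pass (SE 0.26, adjusted p = 0.291). The series title names pmk-1, the skr genes and the lysosome, and the files do not say on which samples the study chose them, so the direction of those lists was not counted as independent evidence. Called downward as well were UDP-glucosyltransferases (0 of 58 past the test, 0 adjusted over the list alone, median -0.52, adjusted p = 0.591 with an estimated correlation), DAF-16 targets and moulting genes. Of 14 DAF-16 targets hsp-12.6 fell and sip-1 rose (6 and 1 adjusted over the list alone), and of 16 moulting genes lrp-1 and fbn-1 fell (4 adjusted over the list alone), both lists with adjusted p = 0.663 with an estimated correlation. With wild-type replicate 2 left out the adjusted p was 0.0533 for tir-1, 0.288 for sek-1, 0.0926 for skr-19, 0.119 for skr-7 and 0.0996 for skr-12. It was 0.139 for fbxb-31, 0.0892 for fbxb-66, 0.0866 for cul-3, 0.293 for fbxc-50, 0.158 for sip-1, 0.181 for hsp-12.6, 0.39 for lrp-1 and 0.135 for fbn-1. The camera adjusted p of the moulting genes was 0.0732 there. Without wild-type replicate 1 sek-1, skr-7, skr-12, fbxb-31, cul-3, fbxc-50, sip-1 and fbn-1 stood at 0.121, 0.0541, 0.156, 0.0541, 0.124, 0.0948, 0.0622 and 0.0682. Without knockout replicate 1 sek-1, skr-7, skr-12, fbxb-31, fbxb-66, fbxc-50 and fbn-1 stood at 0.178, 0.0873, 0.159, 0.0609, 0.0518, 0.117 and 0.125. Without knockout replicate 2 lrp-1 stood at 0.0665, and the log2 fold change of hsp-12.6 at -4.76. Without overexpression replicate 1 skr-7, skr-12, sek-1, fbxc-50, hsp-12.6, lrp-1 and fbn-1 stood at 0.0507, 0.0633, 0.0667, 0.0682, 0.0591, 0.0766 and 0.0611. Without overexpression replicate 2 skr-12, sek-1, fbxc-50, hsp-12.6, lrp-1 and fbn-1 stood at 0.0592, 0.0656, 0.0654, 0.0534, 0.076 and 0.0542.

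The other 22 tested lists were not called in the knockout. Of 100 cuticle collagens 10 rose and 3 fell (15 and 8 adjusted over the list alone), col-19 among the former and col-73 (1.69 ± 0.219 to 0.129 ± 0.182 CPM) among the latter. Of 46 lysosomal hydrolases asp-1, a cathepsin D-like protease, was 1.60-fold higher (0 adjusted over the list alone), and of 21 subunits of the V-ATPase, the proton pump of lysosomes, vha-10 was 1.48-fold higher (1 over the list alone). Of 44 lysosomal membrane genes 0 passed either way. gst-4 was 2.29-fold lower and 2 of 39 glutathione S-transferases fell (1 higher and 2 lower adjusted over the list alone), 2 of 14 SKN-1 targets fell (1 and 2), and prdx-2 rose and sod-4 fell among 28 antioxidant enzymes (1 and 1). Cytosolic heat shock proteins had 3 of 19 higher and 1 lower (6 and 2), nuclear respiratory chain genes 3 of 31 higher (4 and 0, atp-4 2.16-fold), histones 2 of 27 higher (2 and 0) and autophagy genes 1 of 25 lower (epg-2, 0 and 1). Intestine markers had act-5 higher among 12 (2 and 0), neuron markers tbh-1 among 52 (1 and 0) and insulin-like peptides ins-31 among 25 (1 and 1). 0 members passed among 56 cytochrome P450 enzymes, 5 intracellular pathogen response genes, 13 endoplasmic reticulum chaperones, 7 mitochondrial stress genes, 80 lipid metabolism genes, 15 body wall muscle markers, 12 pharynx markers and 12 zygotic embryo genes, with 1 pathogen response gene lower and 1 muscle marker higher adjusted over the list alone. The direction given by camera was up for cytosolic heat shock proteins, with a median of -0.12, and for endoplasmic reticulum chaperones, with a median of -0.088, and neither list was called. Collagens, lysosomal hydrolases and lipid metabolism genes had medians of 0.15, 0.065 and 0.048 but means of -0.26, -0.10 and -0.0042, and the V-ATPase a median of -0.00075 and a mean of 0.011. asp-1 stood at an adjusted p of 0.228 without wild-type replicate 1, 0.0766 without overexpression replicate 1 and 0.0695 without overexpression replicate 2. vha-10 and sod-4 stood at 0.327 and 0.327 without wild-type replicate 2, at 0.0989 and 0.0729 without wild-type replicate 1, at 0.0834 and 0.209 without knockout replicate 1, at 0.0712 and 0.0757 without overexpression replicate 1, and at 0.0697 and 0.0701 without overexpression replicate 2. When wild-type replicate 2 was left out gst-4, atp-4, act-5, tbh-1, ins-31 and epg-2 stood at 0.151, 0.0628, 0.0791, 0.173, 0.105 and 0.155. Without knockout replicate 1 gst-4, tbh-1, ins-31 and epg-2 stood at 0.0938, 0.054, 0.137 and 0.0645. gst-4, tbh-1 and ins-31 stood at 0.056, 0.122 and 0.0615 without wild-type replicate 1, epg-2 at 0.0667 and 0.0594 without overexpression replicates 1 and 2. col-73 had 0 reads in knockout replicate 1, so without knockout replicate 2 no fold was measured.

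In animals with extra gst-35, 15 of 46 lysosomal hydrolases rose and 2 fell, 36 of 100 cuticle collagens rose and 1 fell, and 78 of 105 fbxb genes and 10 of 20 skr genes fell. asp-1, a cathepsin D-like protease, rose from 1507 ± 425 to 5805 ± 799 CPM (n = 2), 3.85-fold (log2 fold change 1.95, SE 0.18, adjusted p = 6.49e-05). T24B8.5, a toxin-like immune peptide that depends on pmk-1, rose 15.7-fold from 1.72 ± 0.822 to 27.005 ± 4.63 CPM (adjusted p = 0.000137). skr-8 fell 9.95-fold, from 32.7 ± 1.01 to 3.29 ± 0.301 CPM (adjusted p = 0.000144). Of 14983 tested genes 2557 changed, 1325 higher and 1232 lower, a share of 51.8% higher that was 64% (526 and 296) without overexpression replicate 2 and between 51.6% and 56.3% without each of the others. With library totals alone the share higher was 28.7%, with 2825 genes past the test. With a 2-fold minimum 578 genes were higher and 929 lower. The largest rises after gst-35 were in Y65B4BR.1 (17.6-fold), T24B8.5, F49F1.6 (10.3-fold), dod-21 (9.77-fold), T01D3.6 (9.50-fold), F55G11.6 (9.22-fold), Y39B6A.1 (9.14-fold), clec-66 (8.98-fold) and clec-190 (8.85-fold). T01D3.6 reached 2616 ± 501 CPM from 275 ± 33.7, and clec-66 reached 744 ± 33.4 from 82.9 ± 33.2. The largest falls were in B0205.13 (31.7-fold lower), Y106G6D.2 (22.05-fold), F58G6.9 (21.8-fold), clec-5 (19.0-fold), hsp-12.6 (18.1-fold), F59B2.12 (15.6-fold), F46E10.2 (15.5-fold), sdz-33 (14.5-fold), fbxb-24 (14.4-fold) and fbxb-1 (14.4-fold). Without overexpression replicate 2 only 822 genes passed, and without wild-type replicates 1 and 2 and overexpression replicate 1 1609, 1127 and 1478. B0205.13, F58G6.9 and F59B2.12 stood at adjusted p of 0.0854, 0.0816 and 0.135 without overexpression replicate 1 and at 0.0746, 0.0746 and 0.0982 without overexpression replicate 2, and F59B2.12 at 0.168 without wild-type replicate 1.

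**Figure D2:**
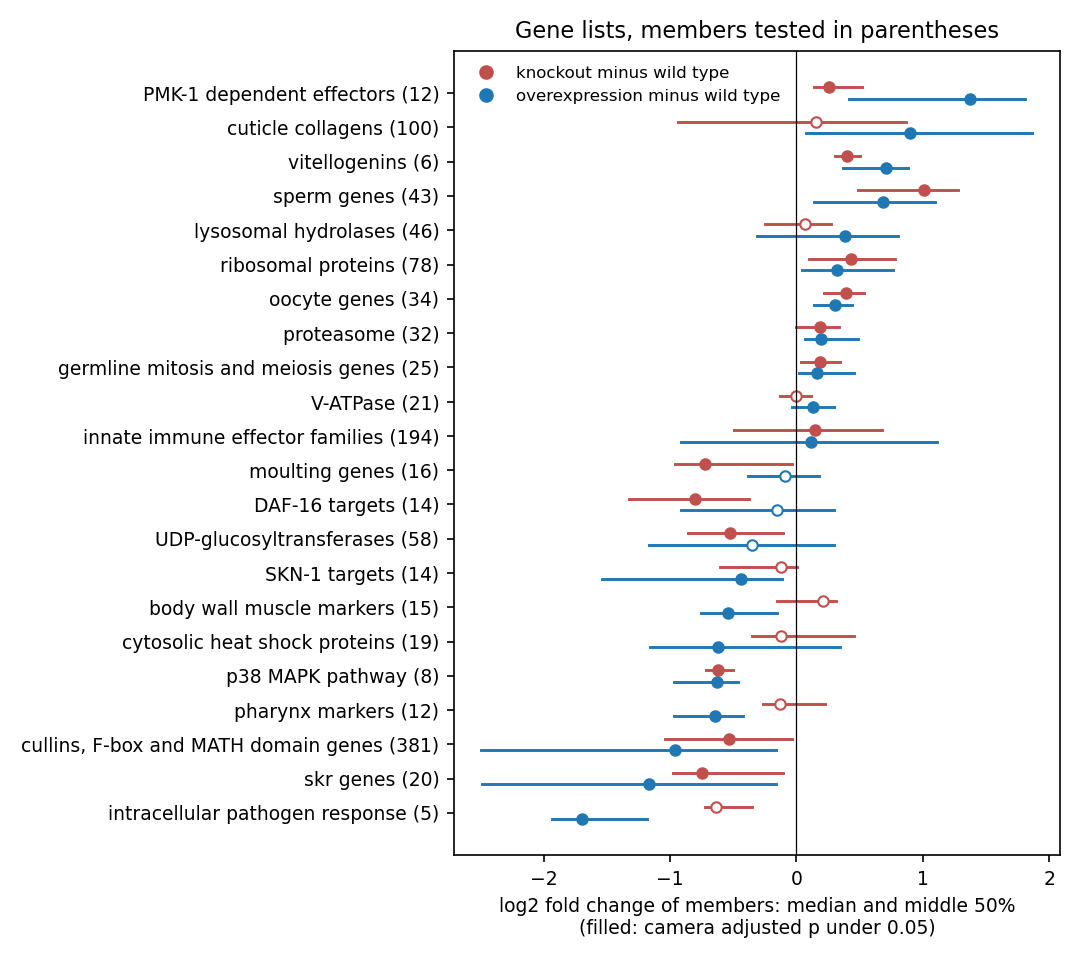
Median log2 fold change of the tested members of each gene list against wild type, with lines over the middle 50% of members, for lists called in either comparison. Filled points passed camera with a preset correlation, a call that no list kept with an estimated correlation, and with library totals alone the medians of immune effectors in both strains and of the V-ATPase and germ cell genes in the overexpression strain lie below 0.

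Lysosomal hydrolases were called upward in the overexpression strain, with 15 of 46 members higher and 2 lower (21 and 3 adjusted over the list alone). asp-1 and asp-3 rose 3.85-fold and 3.06-fold, while the peptidase pcp-3 and the mannosidase aman-1 were 1.84-fold and 2.08-fold lower (camera adjusted p = 5.35e-05, adjusted p = 0.551 with an estimated correlation). Of 21 V-ATPase subunits 3 rose (3 adjusted over the list alone), vha-15 by 2.68-fold and vha-10 by 1.77-fold, with a median of 0.13 (camera adjusted p = 0.035, adjusted p = 0.551 with an estimated correlation). The lysosomal membrane list was not called, with 4 of 44 higher and 2 lower (4 and 2 adjusted over the list alone), scav-4 by 2.71-fold and ppk-3 by 1.71-fold. Nor was autophagy, with atg-16.1 3.63-fold higher and epg-2 3.47-fold lower among 25 (1 higher and 2 lower over all genes, 1 and 1 adjusted over the list alone). The lysosome is named in the series title, so these lists were not counted as independent evidence. Of 100 cuticle collagens 36 rose and col-68 fell (40 and 2 adjusted over the list alone), with col-95 4.18-fold and col-184 3.04-fold higher and a median of 0.90 (camera adjusted p = 1.18e-10, adjusted p = 0.551 with an estimated correlation). Of 12 pmk-1 dependent effectors 8 rose and clec-60 fell (8 and 1 adjusted over the list alone), with clec-85 3.51-fold higher (camera adjusted p = 1.95e-09, adjusted p = 0.467 with an estimated correlation). Immune effector families moved both ways, 46 of 194 higher and 27 lower (55 and 36 adjusted over the list alone). clec-186 and clec-66 rose 7.13-fold and 8.98-fold, clec-5 and clec-10 fell 19.0-fold and 10.5-fold, and camera called the list upward (adjusted p = 0.0241, adjusted p = 0.467 with an estimated correlation) with a median of 0.12 and a mean of -0.11. With overexpression replicate 2 left out the adjusted p was 0.225 for pcp-3, 0.316 for aman-1, 0.137 for ppk-3, 0.0892 for col-68, 0.131 for clec-60 and 0.0708 for the immune list. With wild-type replicate 2 left out pcp-3, aman-1, ppk-3 and clec-60 stood at 0.0623, 0.261, 0.12 and 0.0678, the immune list at 0.12 and the V-ATPase at 0.0788. Without wild-type replicate 1 pcp-3 and aman-1 stood at 0.106 and 0.0514. Without overexpression replicate 1 the V-ATPase stood at 0.0663 and the log2 fold change of pcp-3 at -1.404. With library totals the V-ATPase stood at 0.17 with a median of -0.043 and the immune list had a median of -0.054. The median of the V-ATPase was 0.272 without wild-type replicate 1 and 0.0803 without overexpression replicate 1, and that of cuticle collagens 0.586 and 1.37 without overexpression replicates 1 and 2. That of the innate immune effector families was 0.2001 without wild-type replicate 1, 0.0611 and 0.0699 without knockout replicates 1 and 2, and 0.03697 and 0.0374 without overexpression replicates 1 and 2.

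Ribosomal proteins were called upward again, with 37 of 78 higher and 7 lower (41 and 8 adjusted over the list alone). rpl-41 rose 3.24-fold, rpl-24.1 2.76-fold, and rpl-23 fell 1.76-fold (camera adjusted p = 1.23e-11, adjusted p = 0.551 with an estimated correlation). The proteasome had 8 of 32 higher (10 adjusted over the list alone), pbs-1 and pbs-2 by 1.74-fold each (adjusted p = 0.551 with an estimated correlation), and the vitellogenins 2 of 6 higher (4 adjusted over the list alone), vit-1 by 1.81-fold and vit-6 by 1.47-fold (adjusted p = 0.551 with an estimated correlation). Of 34 oocyte genes 11 rose and cpg-8 fell (16 and 2 adjusted over the list alone), perm-2 by 3.99-fold to 1723 ± 107 CPM and perm-4 by 1.79-fold. Of 25 germ cell genes 6 rose (7 adjusted over the list alone), glh-1 by 1.52-fold and nos-3 by 1.42-fold, and of 43 sperm genes ssp-11 and ssp-37 rose (0 adjusted over the list alone), so that all 3 germline lists were called upward (adjusted p = 0.613 with an estimated correlation for each). Body wall muscle and pharynx markers were called downward, with 3 of 15 lower (3 adjusted over the list alone) and 4 of 12 lower (6 adjusted over the list alone). myo-3, a body wall myosin heavy chain, fell 3.51-fold from 201 ± 59.4 to 57.3 ± 38.9 CPM, mlc-3 1.81-fold, myo-2, the pharyngeal myosin, 2.35-fold and tnc-2 1.89-fold (adjusted p = 0.613 with an estimated correlation for both lists). Overexpression replicate 2 decided the muscle call, which without it had a median of -0.093 and a camera adjusted p of 0.886. Without it the pharynx list stood at 0.225, mlc-3, tnc-2, myo-2, vit-6, ssp-11, ssp-37, glh-1 and nos-3 at 0.215, 0.156, 0.201, 0.0735, 0.0664, 0.216, 0.0523 and 0.0676, and the log2 fold change of myo-3 at -1.20. Without overexpression replicate 1 myo-3 and myo-2 stood at -2.75 and -2.04, and vit-6, tnc-2, cpg-8, ssp-11, ssp-37 and nos-3 at an adjusted p of 0.202, 0.0579, 0.162, 0.113, 0.0565 and 0.0676. With wild-type replicate 2 left out the pharynx, germ cell and sperm lists stood at 0.0691, 0.0551 and 0.223, and mlc-3, tnc-2, myo-2, cpg-8, ssp-11, ssp-37 and nos-3 at 0.0789, 0.151, 0.164, 0.158, 0.133, 0.149 and 0.0797. Without wild-type replicate 1 vit-6, tnc-2, ssp-37 and nos-3 stood at 0.148, 0.0684, 0.109 and 0.0892. With library totals the germ cell list had a median of -0.012 and an adjusted p of 0.107.

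By number of genes, the largest fall among the lists in the overexpression strain was in ubiquitin ligase genes. Of 381 cullin, F-box and MATH domain genes 123 fell and 7 rose (152 and 7 adjusted over the list alone), with a median log2 fold change of -0.96 (camera adjusted p = 2.21e-14, adjusted p = 0.467 with an estimated correlation). The fall lay mainly in the F-box genes of the fbxb and fbxc families. Of 105 fbxb genes 78 were lower, at a median of -2.91 (-2.90 with genes at 0 reads set to a floor of 3 reads per group), and of 40 fbxc genes 17. Of 159 fbxa genes 17 were lower (median -0.554) and of 28 math genes 6 (median -0.863), and differences between families were not tested. Of 6 cullins 0 fell. fbxb-71 fell 18.7-fold and fbxb-75 9.66-fold, while fbxc-50 and fbxa-170 rose 2.303-fold and 1.93-fold. Of 20 skr genes 10 fell (12 lower and 1 higher adjusted over the list alone) with a median of -1.16 (camera adjusted p = 5.99e-09, adjusted p = 0.551 with an estimated correlation). Their falls were 9.95-fold in skr-8, 9.51-fold in skr-10, 8.34-fold in skr-13, 7.78-fold in skr-15, 7.13-fold in skr-9, 5.18-fold in skr-12, 4.85-fold in skr-7, 4.37-fold in skr-14, 2.69-fold in skr-21 and 2.07-fold in skr-19. skr-1, the most abundant member, stood at 184 ± 14.5 CPM against 151 ± 8.02 in wild type and did not pass (adjusted p = 0.177), and skr-2, skr-3, skr-4, skr-5, skr-11, skr-16, skr-17, skr-18 and skr-20 did not pass either, with log2 values from -1.28 to 0.66. Several fbxb and skr genes are near-identical copies of each other, so their separate values are uncertain. In the p38 pathway sek-1 fell 2.05-fold and tir-1 1.97-fold, and 4 of 8 genes were lower (5 adjusted over the list alone, camera adjusted p = 0.00703, adjusted p = 0.551 with an estimated correlation). The other 2, pmk-2 at a log2 fold change of -0.97 and pmk-3 at -0.69, were picked after their values were seen. pmk-2 and pmk-3 stood at an adjusted p of 0.0893 and 0.178 without wild-type replicate 1, 0.111 and 0.119 without wild-type replicate 2, 0.0956 and 0.119 without overexpression replicate 1, and 0.101 and 0.139 without overexpression replicate 2. pmk-1 stood at 18.5 ± 7.57 CPM, a log2 difference of -0.56 that did not pass (SE 0.26, adjusted p = 0.168). As in the knockout, the skr and p38 lists were not counted as independent evidence. The median of the skr genes was -0.747 without wild-type replicate 2. Without overexpression replicate 2 the adjusted p was 0.0865 for tir-1, 0.126 for fbxa-170, 0.099 for skr-19 and 0.191 for skr-21. Without overexpression replicate 1 it was 0.132 for skr-19 and 0.105 for skr-21. Without wild-type replicate 2 it was 0.121 for fbxa-170, 0.108 for skr-19 and 0.0523 for skr-21, and without wild-type replicate 1 it was 0.0559 for skr-21. Genes under 1 CPM had a median log2 fold change of -0.66 in this comparison, and the 4182 genes over 50 CPM one of 0.113, with 668 higher and 186 lower.

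**Figure D3:**
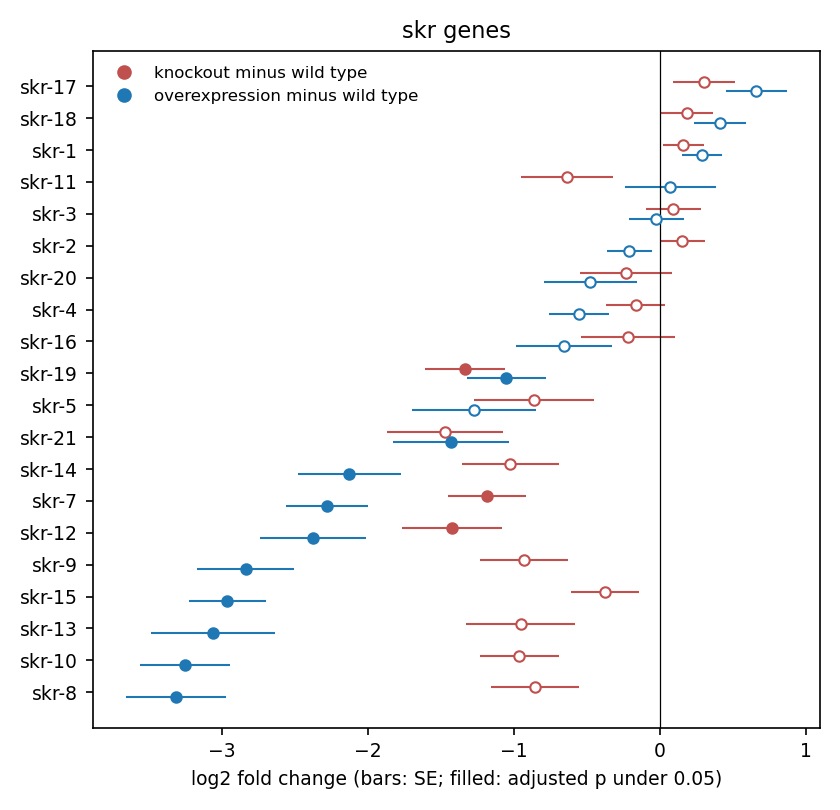
Log2 fold change of each tested skr gene in the knockout and in the overexpression strain against wild type, with bars of 1 SE and filled points where the adjusted p passed the threshold. In the overexpression strain 10 of 20 fell and in the knockout 3 of 20 fell, and with library totals alone skr-2 and skr-3 in the knockout and skr-11 in the overexpression strain, none of which passed, change sign.

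Stress-response lists fell in part with overexpression. Of 19 cytosolic heat shock proteins 6 fell and 2 rose (10 and 4 adjusted over the list alone), with hsp-16.41 and hsp-16.2 2.24-fold and 2.13-fold lower and sip-1 and dnj-13 1.52-fold and 1.32-fold higher (camera adjusted p = 0.0489, adjusted p = 0.551 with an estimated correlation). Of 14 SKN-1 targets 6 fell and gst-38 rose (7 and 1 adjusted over the list alone), gst-30 by 3.82-fold and gst-4 by 2.91-fold (camera adjusted p = 0.0204, adjusted p = 0.551 with an estimated correlation). In the intracellular pathogen response B0284.1 and F26F2.3 fell among 5 genes (3 lower adjusted over the list alone, camera adjusted p = 0.0368, adjusted p = 0.551 with an estimated correlation). The remaining lists were not called. Glutathione S-transferases had 3 of 39 higher and 6 lower (3 and 7 adjusted over the list alone), gst-38 by 3.94-fold and gst-30, UDP-glucosyltransferases 9 of 58 each way (10 and 11, ugt-12 3.88-fold higher, ugt-64 2.69-fold lower) and cytochrome P450 enzymes 9 of 56 higher and 4 lower (10 and 4, cyp-34A2 15.1-fold higher). Lipid metabolism genes had 10 of 80 higher and 6 lower (10 and 6), with the desaturase fat-6 2.11-fold higher and cpt-6 2.43-fold lower. Antioxidant enzymes had 1 of 28 higher, prdx-2 by 2.29-fold, and 4 lower (3 and 6), insulin-like peptides 1 of 25 higher and 7 lower (1 and 9, ins-7 3.81-fold lower) and neuron markers 2 of 52 higher and 4 lower (1 and 3, tbh-1 2.06-fold higher). Respiratory chain genes had 7 of 31 higher and 1 lower (8 and 1, asb-2 2.76-fold higher), DAF-16 targets 1 of 14 higher and 2 lower (1 and 2), histones 2 of 27 higher (1 and 0), endoplasmic reticulum chaperones 1 of 13 higher (0 and 0), intestine markers 1 of 12 higher (1 and 0, act-5) and zygotic embryo genes 2 of 12 lower (0 and 3). 0 of 7 mitochondrial stress genes and 0 of 16 moulting genes passed, with 0 adjusted over either list alone. Lipid metabolism genes, called neither way, had a camera direction up with a median of -0.0071, intestine markers up with -0.054, and autophagy up with a mean of -0.019. The heat shock list stood at 0.0746 without overexpression replicate 2, at 0.129 without overexpression replicate 1, at 0.0802 without wild-type replicate 1, and at 0.05 with median-of-ratios size factors. The pathogen response list stood at 0.127, 0.0971, 0.0583 and 0.0588 without overexpression replicate 2, wild-type replicate 2, and knockout replicates 1 and 2, and at 0.0615 with library totals. The SKN-1 list stood at 0.0551 without wild-type replicate 2. With overexpression replicate 2 left out B0284.1, F26F2.3, sip-1, dnj-13, cpt-6 and ins-7 stood at 0.193, 0.253, 0.108, 0.183, 0.0781 and 0.0574. With overexpression replicate 1 left out B0284.1, F26F2.3, dnj-13 and act-5 stood at 0.0613, 0.0585, 0.103 and 0.0539. With wild-type replicate 2 left out B0284.1, F26F2.3, sip-1 and dnj-13 stood at 0.0855, 0.107, 0.0779 and 0.083. Without wild-type replicate 1 B0284.1, F26F2.3 and dnj-13 stood at 0.145, 0.182 and 0.26, and without knockout replicates 1 and 2 F26F2.3 at 0.0513 and 0.0607.

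Between the overexpression and knockout strains, which share no library, 927 genes differed, 512 higher with overexpression and 415 lower, a share of 55.2% higher. That share was 44.1% (484 and 614) without knockout replicate 1, 63.3% (578 and 335) without knockout replicate 2, 74% (248 and 87) without overexpression replicate 2 and between 53.3% and 57.9% without each of the others. Of 46 lysosomal hydrolases 9 were higher with overexpression, of 100 collagens 23 were higher and 3 lower, and 26 of 105 fbxb and 6 of 20 skr genes were lower. After gst-35 the largest rises were in T24B8.5 (19.5-fold), the lipase gene lipl-2 (18.9-fold, 0.791 ± 0.536 to 14.9 ± 3.52 CPM, n = 2), F54G2.2 (17.1-fold), F23D12.11 (15.2-fold), dod-21 (9.56-fold), hbl-1 (9.08-fold), Y22D7AR.10 (8.87-fold), clec-190 (8.29-fold) and Y39B6A.1 (7.64-fold). hbl-1, a transcription factor of developmental timing, stood at 45.7 ± 7.21 CPM against 5.03 ± 0.253 (log2 fold change 3.18, SE 0.24, adjusted p = 3.12e-05). The largest falls were in F59B2.12 (122-fold lower), clec-5 (12.83-fold), F58G6.9 (12.82-fold), Y106G6D.2 (10.9-fold), clec-10 (9.39-fold), the Notch ligand gene dsl-2 (7.50-fold), H11L12.1 (7.03-fold), F28C6.1 (6.58-fold), fog-3, a sperm fate gene of the germline (6.11-fold), and the 5.8S ribosomal RNA gene rrn-2.1 (6.07-fold). F59B2.12 stood at 0.144 ± 0.127 CPM against 17.96 ± 7.46 (adjusted p = 0.0013). Without overexpression replicate 1 471 genes passed and without overexpression replicate 2 335. F58G6.9 stood at an adjusted p of 0.221 and 0.206 without overexpression replicates 1 and 2 and 0.536 without knockout replicate 2, dsl-2 and fog-3 at 0.107 and 0.11 without overexpression replicate 2, and the log2 fold change of dsl-2 at -1.78 without knockout replicate 2.

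The lists called in this comparison had adjusted p = 0.65 with an estimated correlation in every case. Upward were cuticle collagens (23 of 100 higher and 3 lower, 39 and 7 adjusted over the list alone, col-95 3.54-fold and col-73 65.5-fold higher, col-68 6.57-fold and col-19 1.74-fold lower), lysosomal hydrolases (9 of 46 higher, 12 higher and 1 lower adjusted over the list alone, asp-3 2.52-fold), pmk-1 dependent effectors (7 of 12 higher and clec-60 lower, 7 and 1 adjusted over the list alone, F35E12.8 3.0995-fold higher) and the V-ATPase (2 of 21, 3 adjusted over the list alone, vha-15 2.72-fold and vha-12 1.54-fold), with adjusted p = 0.65 with an estimated correlation. Cytochrome P450 enzymes (5 of 56 higher and 1 lower, 6 and 1 adjusted over the list alone, cyp-34A2 22.8-fold higher), moulting genes (noah-2 and let-653 higher among 16, 3 adjusted over the list alone) and DAF-16 targets (mtl-2 and fat-5 higher among 14, 3 adjusted over the list alone) were called upward too, with adjusted p = 0.65 with an estimated correlation. Downward were cullin, F-box and MATH genes (36 of 381 lower and fbxa-170 higher, 59 and 1 adjusted over the list alone, fbxb-71 10.8-fold and fbxa-107 3.31-fold lower), the skr genes (6 of 20 lower, 7 adjusted over the list alone), body wall muscle (2 of 15, 4 adjusted over the list alone), cytosolic heat shock proteins (3 of 19, 5 adjusted over the list alone, hsp-70 1.80-fold) and pharynx markers (0 of 12, 0 adjusted over the list alone), with adjusted p = 0.65 with an estimated correlation. Falls were 6.01-fold in skr-15, 5.49-fold in skr-8, 4.88-fold in skr-10, 4.30-fold in skr-13, 3.74-fold in skr-9 and 2.14-fold in skr-7, and 3.05-fold in myo-3 and 2.25-fold in unc-89, an obscurin-like muscle protein. pmk-1 differed by -0.049 (SE 0.27, adjusted p = 0.949). The skr and lysosome lists were not counted as independent evidence here either. Without overexpression replicate 2 the muscle and pharynx lists stood at 0.262 and 0.403, and col-68, col-19, clec-60, let-653, mtl-2, fat-5, fbxa-170, skr-7, skr-13, skr-9, myo-3 and unc-89 at an adjusted p of 0.0846, 0.17, 0.161, 0.0967, 0.0988, 0.151, 0.161, 0.0896, 0.111, 0.0728, 0.0852 and 0.16. Without overexpression replicate 1 the moulting and DAF-16 lists stood at 0.23 and 0.116, vha-12, noah-2, let-653, fat-5, hsp-70, col-68, skr-7 and skr-13 at 0.177, 0.149, 0.143, 0.0593, 0.0594, 0.0507, 0.224 and 0.0887, and the log2 fold changes of myo-3 and unc-89 at -2.56 and -1.97. Without knockout replicate 1 the moulting, DAF-16 and cytochrome P450 lists stood at 0.211, 0.501 and 0.091, and vha-12, noah-2, let-653 and fbxa-170 at 0.0504, 0.0726, 0.084 and 0.0662. Without knockout replicate 2 the pharynx and heat shock lists stood at 0.0543 each, skr-7 at 0.209, and the log2 fold change of skr-13 at -1.23. col-73 had 0 reads in knockout replicate 1, so its fold without knockout replicate 2 was not measured.

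The other 24 tested lists were not called between overexpression and knockout. Members past the test were 6 higher and 2 lower of 58 UDP-glucosyltransferases (10 and 4 adjusted over the list alone, ugt-12 4.38-fold higher), 30 and 20 of 194 immune effectors (39 and 36, clec-190 higher and clec-10 lower), 8 and 4 of 80 lipid metabolism genes (13 and 8, fat-6 1.78-fold higher), 2 and 1 of 78 ribosomal proteins (1 and 1, rpl-27 1.57-fold higher, rla-0 1.56-fold lower) and 1 and 1 of 34 oocyte genes (1 and 1, perm-2 1.45-fold higher). 2 of 39 glutathione S-transferases were lower (0 and 2, gst-30 3.78-fold), 2 of 14 SKN-1 targets (0 and 2), 2 of 25 insulin-like peptides (0 and 2, ins-31 38.6-fold) and 1 of 28 antioxidant enzymes (0 and 1, trx-3). asb-2 was 2.88-fold higher among 31 respiratory chain genes (1 and 0), atg-16.1 5.68-fold among 25 autophagy genes (1 and 0), pgp-3 2.17-fold among 12 intestine markers (1 and 0) and tbh-1 1.38-fold among 52 neuron markers (0 and 0). 0 members passed, over all genes or over the list alone, among lysosomal membrane, p38, pathogen response, chaperone, mitochondrial stress, proteasome, vitellogenin, sperm, germ cell, zygotic embryo and histone genes. ctb-1, the only tested member of the mitochondrial genome list, was 1.45-fold higher with overexpression, and camera was not run on that list. Immune effectors had a camera direction up with a median of -0.0092, as did respiratory chain (-0.088), ribosomal (-0.035), lipid (-0.027) and germ cell genes (-0.061), and histones were down with a mean of 0.12. Without overexpression replicate 2 rpl-27, rla-0, perm-2, trx-3, pgp-3, tbh-1 and ctb-1 stood at an adjusted p of 0.0584, 0.165, 0.196, 0.179, 0.0517, 0.305 and 0.233, and without overexpression replicate 1 perm-2, trx-3, pgp-3, tbh-1 and ctb-1 at 0.0867, 0.0529, 0.233, 0.0903 and 0.0797. Without knockout replicate 1 pgp-3 and ctb-1 stood at 0.0756 and 0.0669, without knockout replicate 2 trx-3 and tbh-1 at 0.0826 and 0.128, and without wild-type replicates 1 and 2 tbh-1 at 0.0669 and 0.0628.

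Knockout and overexpression lie on opposite sides of wild type for gst-35, and the genes that changed in both comparisons were set side by side. 471 genes changed in the same direction in both, 331 higher and 140 lower, against 39.5 and 17.6 for independent lists of these sizes. 13 changed in opposite directions, 5 higher in the knockout and lower with overexpression and 8 the reverse, against 36.8 and 18.9 for independent lists. Both comparisons use the same wild-type libraries, which can add to such an overlap. In the simulations of unchanged groups at most 0 genes were called in both comparisons, in the same or in opposite directions. Unchanged groups give few calls, so that count does not measure what the sharing adds among changed genes. Across genes the log2 fold changes correlated at 0.48, and those of 20 simulations of unchanged groups against those libraries at 0.485, and their covariance was 0.384 against 0.1 simulated, a difference of 0.284. F49F1.6, perm-2, prdx-2, C55C3.3 and rpl-24.1 rose in both strains, and F59C12.4 and H19N07.3 fell in both. Besides gst-35, the genes lower in the knockout and higher with overexpression were C08F11.11 (log2 fold changes -0.92 and 1.05), cat-4, a GTP cyclohydrolase (-0.84 and 0.94), F23D12.11 (-2.22 and 1.71), C26B9.3 (-2.37 and 2.74) and the collagens col-73 (-3.61 and 2.43), dpy-13 (-4.65 and 2.55) and col-17, which had 0 reads in the knockout. Higher in the knockout and lower with overexpression were F59B2.12 (2.97 and -3.96), clec-219 (2.99 and -3.98), C48B4.12 (2.96 and -3.98), ins-31 (2.16 and -3.11) and C17C3.5 (1.93 and -2.64). The names of the genes that moved in opposite directions were drawn from that count after the values were seen. Only gst-35 and C08F11.11 kept both calls with each library left out. The adjusted p of the knockout calls without wild-type replicate 1 was 0.0615 for F23D12.11, 0.0615 for ins-31, 0.056 for C17C3.5 and 0.267 for cat-4. With wild-type replicate 2 left out it was 0.105 for ins-31, 0.152 for C17C3.5, 0.127 for C26B9.3, 0.135 for C48B4.12, 0.0892 for cat-4, 0.148 for clec-219, 0.113 for col-17 and 0.0701 for dpy-13. With knockout replicate 1 left out it was 0.137 for ins-31, 0.239 for C17C3.5, 0.124 for C48B4.12, 0.0519 for cat-4, 0.215 for clec-219, 0.0549 for col-17 and 0.0611 for dpy-13, and with knockout replicate 2 left out 0.0921 for cat-4. Left out, overexpression replicate 1 gave 0.0505 for C17C3.5, 0.0522 for F59B2.12, 0.0786 for cat-4 and 0.0644 for col-17, and replicate 2 gave 0.0776 for cat-4 and 0.0523 for col-17. The overexpression calls stood at 0.158 for C48B4.12, 0.168 for F59B2.12, 0.176 for clec-219 and 0.175 for col-17 without wild-type replicate 1, and at 0.0553 for F23D12.11 and 0.0956 for cat-4 without wild-type replicate 2. When overexpression replicate 1 was left out they stood at 0.0667 for C17C3.5, 0.0718 for C48B4.12, 0.135 for F59B2.12, 0.0578 for cat-4, 0.0868 for clec-219, 0.201 for col-17, 0.0603 for col-73 and 0.0893 for dpy-13. When overexpression replicate 2 was left out they stood at 0.0509 for C17C3.5, 0.18 for C48B4.12, 0.0718 for F23D12.11, 0.0982 for F59B2.12, 0.209 for clec-219, 0.119 for col-17 and 0.0609 for ins-31. col-73 and dpy-13 had 0 reads in knockout replicate 1 and C48B4.12 and clec-219 had 0 in overexpression replicate 2, so no fold was measured for them without the other library of the group. The log2 fold changes in the knockout were 1.19 for C17C3.5 without knockout replicate 1 and 5.09 for F59B2.12 without wild-type replicate 1. That of F59B2.12 with overexpression was -1.82 without wild-type replicate 1. The count in the same direction was 69 without wild-type replicate 2, 161 without wild-type replicate 1, 1004 without knockout replicate 2, and 238 and 194 without overexpression replicates 1 and 2, and the count in opposite directions lay between 4 without wild-type replicate 2 and 40 without knockout replicate 2.

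**Figure D4:**
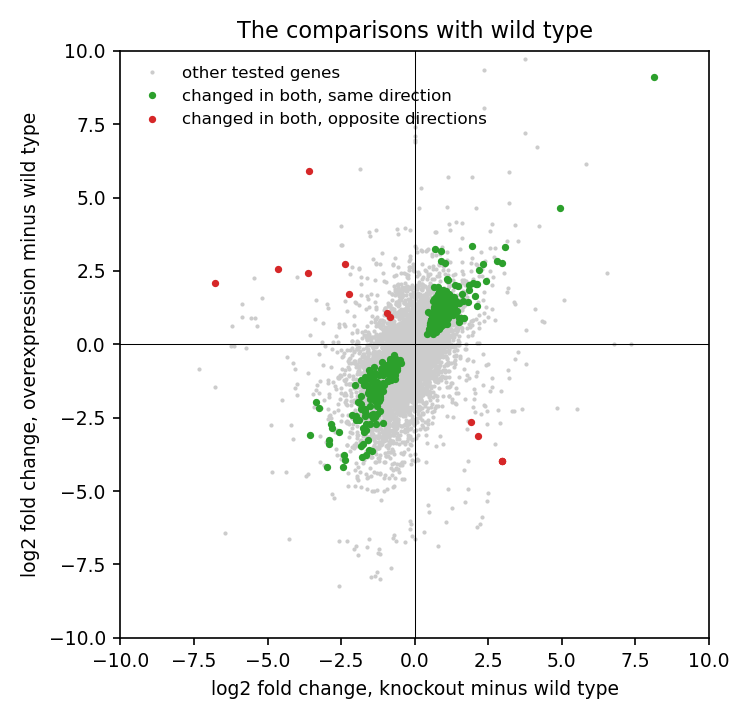
Log2 fold change of each tested gene in the overexpression strain (vertical) against that in the knockout (horizontal), both relative to wild type. The 471 genes changed in the same direction in both are green and the 13 changed in opposite directions are red.

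Genes higher with overexpression than in the knockout were more frequent on chromosome X than elsewhere, a split looked at after the values were seen. Among genes with a mean of at least 5 CPM, 129 of 1184 X-linked genes (10.9%) and 262 of 7825 autosomal genes (3.35%) were higher (odds ratio 3.53, Fisher's exact test p = 2.5e-25, across genes that are not independent). Against wild type the overexpression strain had 191 of 1184 X-linked and 965 of 7825 autosomal genes higher and 110 and 546 lower, an odds ratio of 1.37 in both directions. The knockout had 28 X-linked and 389 autosomal genes higher and 32 and 121 lower, with odds ratios of 0.463 for higher and 1.77 for lower. The X-linked genes with the smallest p included pqn-65 (126 to 843 CPM in the means of 2 libraries, log2 fold change 2.74, SE 0.16), R07E4.5, sft-4, pak-1, spat-3 and hbl-1, which lie between 4595997 and 6048608 on the deposited coordinates. These genes, picked for their difference from the knockout, also rose with overexpression against wild type. Their log2 fold changes there ran from 1.72 in pak-1 to 2.72 in R07E4.5, with 2.53 in pqn-65. Between 1 and 6 Mb 67 of 335 genes were higher, against 62 of 849 elsewhere on X. The median of X-linked genes minus that of autosomal genes, each library against the mean of all, was -0.25 in knockout replicate 1 and between -0.082 and 0.15 in the other libraries, and without overexpression replicate 1 or 2 the X-linked genes higher numbered 70 and 74.

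**Figure D5:**
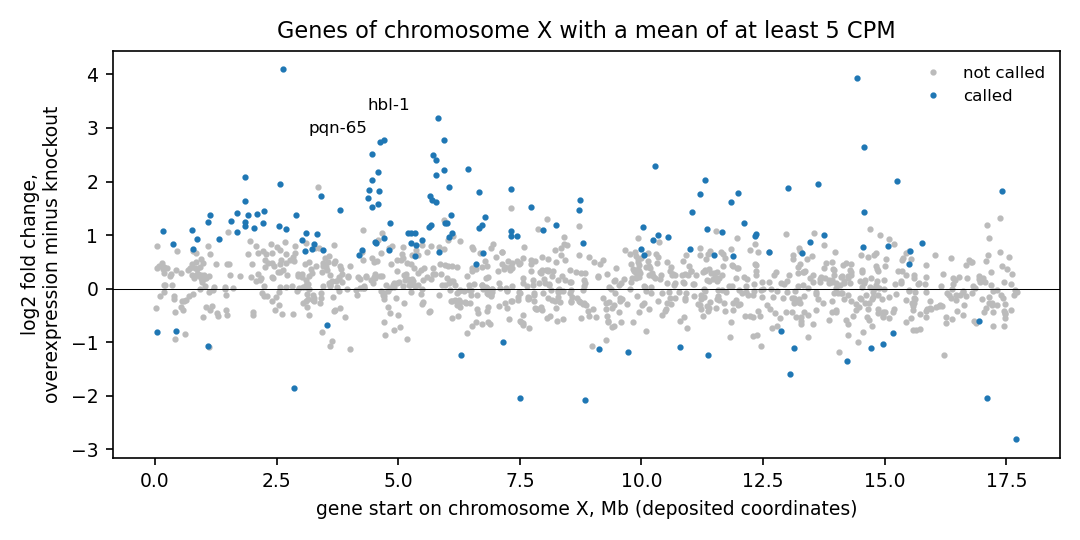
Log2 fold change between overexpression and knockout of genes on chromosome X with a mean of at least 5 CPM, by gene start in megabases. Blue points passed the test, 129 of them higher and 23 lower, and pqn-65 and hbl-1 are marked.

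The authors' deposited table lists 743 genes up and 1308 down for overexpression against wild type, and 624 up and 644 down for overexpression against knockout. Its values show that these lists hold genes with an unadjusted p under 0.05 and an absolute log2 fold change over 1. Of the genes that the authors list against wild type 151 and 546, and of those listed against the knockout 211 and 376, have an adjusted p of 0.05 or more in the authors' deposited values. Of the listed genes 592 up and 904 down against wild type, and 376 up and 331 down against the knockout, were among those called here in the same direction, with 0 called in the opposite direction. The log2 fold change of gst-35 in the authors' deposited table is 5.94 against wild type and 9.57 against the knockout.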

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

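The alternatives in this part were chosen before the data were examined. The runs on separate wild-type libraries, and those on chromosome X, on somatic markers, on 4 gene families and on genes named outside the rule without each library, are given elsewhere and were added after seeing the data. The 2-fold minimum was applied to counts of genes only, and the statements on single genes cover the other alternatives, in which gst-35 kept its direction and its call, with log2 fold changes from -4.72 to -2.995 in the knockout, 5.87 to 6.01 with overexpression and 8.92 to 10.64 between the strains when libraries were left out. Of 221 called values of named genes none changed direction under an alternative, and 2721 of their alternative values stayed past the threshold while 357 did not. Apart from the 2-fold minimum, all alternatives that tested the gene kept the calls of 18 of 60 named genes in knockout against wild type, 63 of 99 in overexpression against wild type and 34 of 65 in overexpression against knockout.

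Counts of changed genes moved by more than 1.5 times in these settings. In knockout against wild type (661) DESeq2 called 1199, no low-count filter 1622, only the groups compared 253 and a 2-fold minimum 283. In overexpression against wild type (2557) a 2-fold minimum left 1507, and in overexpression against knockout (927) no filter gave 1659. The count changed in the same direction in both comparisons with wild type (471) was 782 with DESeq2, 1045 with no filter and 159 with the 2-fold minimum. The count in opposite directions (13) was 21, 5, 42, 8 and 20 with DESeq2, limma-voom, no filter, at least 5 CPM in 2 libraries and the replicate block. With no filter 24114 genes were tested. With only the groups compared the spread came from 4 libraries, and the genes tested numbered 14627, 14500 and 13983 in the 3 comparisons. For DESeq2 the cause was not tested. With a library left out the counts lay between 94 (without wild-type replicate 2) and 1555 (without knockout replicate 2), between 822 (without overexpression replicate 2) and 3305 (without knockout replicate 1), and between 335 (without overexpression replicate 2) and 1098 (without knockout replicate 1) in the 3 comparisons. They lay between 69 and 1004 for the same direction and between 4 and 40 for opposite directions, lowest without wild-type replicate 2 and highest without knockout replicate 2. Leaving out a library of a group not compared also moved the counts. This changed both the shared estimate of the spread and the genes that passed the filter (15811 to 16193 against 14983), and the cause was not tested.

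Camera called 14, 19 and 12 lists. With an estimated correlation it called 0, 0 and 0, and the directional test of fry called 0, 0 and 0. With a library left out it called 11 to 15, 13 to 19 and 11 to 14, and no called list changed direction.

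Sign changes occurred only in genes that did not pass, 37 in all, and the cause was not tested. limma-voom gave gst-28 in the knockout 0.04231. Library totals gave skr-3 and skr-2 in the knockout -0.06091 and -0.005929 and skr-11 with overexpression -0.1088, and no filter gave skr-3 with overexpression 0.0264. With a library left out, log2 fold changes in the knockout ran from -0.6162 to 0.142 for skr-16, -0.7883 to 0.174 for skr-20, -0.1123 to 0.366 for skr-3, -0.01615 to 0.3173 for skr-2, -0.3957 to 0.1104 for gst-31, -0.5697 to 0.6541 for gst-28, -0.5533 to 0.2681 for gst-27 and -0.9014 to 0.07734 for gst-29. With overexpression against wild type they ran from -0.1362 to 0.3898 for skr-11, -0.2091 to 0.2695 for skr-3, -0.9093 to 0.3142 for gst-28 and -0.4134 to 0.4076 for gst-27. Between overexpression and knockout they ran from -0.1256 to 0.8526 for skr-19, -0.2785 to 0.05889 for skr-3, -0.5649 to 1.126 for skr-21, -0.01576 to 0.2817 for skr-1, -0.6451 to 0.3157 for skr-20, -0.1612 to 0.4575 for gst-27, -0.544 to 0.4362 for gst-29, -0.5061 to 0.3254 for gst-26 and -0.5445 to 0.3473 for pmk-1.

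The replicate number as a block gave 973, 2722 and 1168 changed genes. The replicates share only their numbers, and deviations of the same number correlated at 0.196, -0.0557 and -0.0683 between groups. Depth limits the genes with few reads: gst-35 itself had 3 and 11 reads in the knockout. Genes under 1 CPM, 2447 in number, had 10 higher and 8 lower calls in knockout against wild type. They had 47 higher and 155 lower calls in overexpression against wild type. Over all 14983 tested genes 1325 were higher and 1232 lower there, so calls were less frequent among the weakly expressed genes.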

Other observations

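The splits and families in this part were chosen after the results were seen, and so were the tests of them. The sdz genes are a family outside the fixed lists, and no enrichment test was run on them. They were first described as SKN-1 dependent zygotic transcripts. Of 28 tested members 15 fell and 1 rose against wild type, with a median log2 fold change of -2.57 (bootstrap interval -3.01 to -1.26 over genes), and 11 fell and 1 rose against the knockout. In the knockout 1 of 28 fell, with a median of -0.76.

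Genes on chromosome X were over-represented among those higher with overexpression than in the knockout, at an odds ratio of 3.53. A single knockout library that stands apart is argued against as the whole cause of these calls, since the odds ratio was 3.06 without knockout replicate 1. The shift of all X-linked genes leaned on that library. Their median minus that of autosomal genes was -0.247 in knockout replicate 1 and 0.00199 in knockout replicate 2. It was 0.148 and -0.0823 in overexpression replicates 1 and 2. A gain of a copy of the whole part from 1 to 6 Mb would raise its genes by 0.585 on the log2 scale. Their median was lower, at 0.271 (interval 0.224 to 0.388). That interval covers the spread between genes and not that between libraries, and the median was not taken again without each library. A gain of the whole part therefore stays open, as do gains of shorter segments. A smaller share of germline would raise somatic markers, and the 79 muscle, pharynx and neuron markers had a median of -0.302 (interval -0.395 to -0.184). It was -0.0374 (-0.106 to 0.0135) without overexpression replicate 2, so this explanation stays open. What set X-linked genes apart between the 2 strains stays open, and no test of a biological cause was run.

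With overexpression 78 of 105 fbxb, 17 of 40 fbxc, 10 of 20 skr and 15 of 28 sdz genes were lower than in wild type, and 0, 2, 0 and 1 higher. Less background spread evenly over silent genes would take no more from a family than from chemoreceptor genes, which lost 0.07 CPM each on average (0.0481 to 0.0903, 1584 genes). fbxb and sdz genes lost 3.59 and 2.68 (intervals 2.91 to 4.37 and 0.332 to 5.34), and lost more than chemoreceptor genes without each library too. This argues against an even background for fbxb and sdz genes only. They were picked for their fall, and the wild-type levels of chemoreceptor genes were not compared, so a background that differs between genes stays open. By the family means an even background stays open for fbxc genes, which lost 1.19 (-0.691 to 2.72). So it does for skr genes, which lost 10.3 (1.95 to 18.8) and 8.54 (-0.113 to 16.8) without wild-type replicate 2. The skr mean takes in skr-1, the most abundant member, which did not fall (log2 fold change 0.286), so it says little of the 10 of 20 that did. A scale factor moves all genes alike, so it cannot set these families apart from the median gene. Library totals were no further test of this. They moved the fold changes by a median of only -0.174, and the families were picked for their fall. With library totals the median of all genes was -0.20, and those of fbxb, fbxc, skr and sdz genes were -3.08 (-3.24 to -2.88), -1.64 (-2.71 to -0.727), -1.33 (-2.5 to -0.512) and -2.74 (-3.18 to -1.53). The intervals also lay under the median of all genes without each library. A first bound, a distance of more than 1 from that median, was set aside after fbxc and skr genes did not meet it, since the explanation allows no distance beyond the spread. A difference in library preparation stays open. Ribosomal RNA took 0.528% and 0.517% of the counts in wild type, 0.240% and 0.405% in the knockout and 0.145% and 0.0856% with overexpression, and the mean fbxb gene stood at 4.38 and 4.92, 1.36 and 2.99, and 0.819 and 0.789 CPM. Over the 6 libraries the rank correlation with that share was 0.943, 0.657, 0.886 and 0.928 for fbxb, fbxc, skr and sdz genes. The share follows the groups, so these correlations cannot separate the 2. A preparation difference would also leave less of each family in the library of a group with less ribosomal RNA. That order held in 2 of 3 groups for fbxb genes and in 1 of 3 for fbxc, skr and sdz genes. In the knockout, with shares of 0.240% and 0.405%, it held for each of these families. In wild type, where the shares lay close at 0.528% and 0.517%, it held for none. With overexpression it held for fbxb genes and not for fbxc and skr genes, and sdz genes tied at 4.88 CPM. This part of the prediction was not met in every group, with only 2 libraries per group to judge it. Fewer early embryos inside the animals stays open: the 12 zygotic embryo genes had a median of -0.599 (interval -1.48 to -0.325), a list that camera did not call (adjusted p = 0.0918). Counts of embryos per animal would separate this from a change in transcription.

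Knockout and overexpression moved away from wild type in the same genes, 471 in the same direction and 13 in opposite directions, although their gst-35 levels lie on opposite sides of wild type. The shared wild-type libraries do not account for all of it, since with a separate wild-type library in each comparison the covariance was still 0.243 (interval 0.225 to 0.26). Weakly expressed genes do not either, since in genes with a mean of at least 5 CPM it was 0.147 (0.135 to 0.16) and 0.161 (0.146 to 0.175) for the 2 ways of dividing these libraries. A difference of the wild-type strain, its culture or its libraries from both edited strains may explain the pattern, as may the gst-35 level, and neither was tested.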
